A study of Mus musculus with 80 samples.

How the data were processed

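The series holds 80 samples of mouse cells, most of them DN2 cells, an early stage of thymocyte development, grown in culture from bone marrow progenitors on the stromal line OP9-DL1 with Flt3-L and IL-7 and then sorted. Samples were grouped by genotype from the labels as wild type, heterozygous ThymoD+/p(A) or homozygous ThymoDp(A)/p(A), and by assay, treatment and time. Values from 55 samples were used. GRO-seq, bisulfite sequencing, nuclear RNA-seq, the input libraries and the RNA-seq of 6 tumours were not analysed here.

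The RNA-seq table holds raw counts per gene symbol as deposited, and the submitters' processing notes list FastQC, STAR, HTSeq and DESeq2 with the build mm10. The labels describe second-strand synthesis with dUTP, and whether HTSeq counted by strand is not given in the sources used here, so overlapping and antisense genes are uncertain. Genes of close families, such as the killer-cell receptor and granzyme genes, can also share reads. HTSeq's categories of reads not assigned to a gene held between 50.4% and 53.1% of each library, and they were left out of library sizes and tests. Reads in no annotated feature made up 7.49% to 11.9% and ambiguous reads 0.394% to 0.416%, so most unassigned reads were in HTSeq's other categories. No column of the table lacked a sample. In 27 places a symbol had turned into a date, and these genes stayed in the test but were not named. Symbols were matched to the GRCm38 gene table for 93.7% of genes, which gave the gene coordinates.

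The region lists hold a chromosome, start and end per region as deposited and no height, score or p-value, so the 46 lists used carry positions only. Per the submitters' processing notes, reads were aligned with Bowtie 1.1.1 and handled with HOMER on the build mm9, and regions were called for each library. The settings of the caller are not given in the sources used here. Regions on the autosomes and X were used. No annotation of mm9 was used here, so regions were not assigned to genes. Coordinates of regions and of DN2 Hi-C bins are those of mm9, and those of genes and of the DN3 matrix are those of mm10, the same assembly as GRCm38. None were converted.

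The Hi-C matrices of DN2 cells are HOMER matrices per the file headers, and their deposited values are log2 ratios of observed over expected contacts. The log base and the pseudocount of 0.5 were checked from the spacing of the lowest values, which was 1.56 and 1.55 in the 2 matrices against 1.58 for that formula. Per the file headers, the p(A)/p(A) matrix was normalised to the wild-type one. Per the series design text, the re-analysed matrices of B-lineage cells and the wild-type matrix were scaled to the shallowest library. A matrix whose header names pre-pro-B cells is listed as multipotent progenitors in that text, and is called pre-pro-B below. The DN3 matrix holds signal, the contacts per pair of 50 kb bins after Knight-Ruiz balancing by the authors per its deposited name. Read depth of the ChIP-seq, ATAC-seq and Hi-C libraries is not given in the sources used here.

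Gene counts were tested with edgeR 4.0.16 in R 4.3.3, comparing p(A)/p(A) with wild type by the quasi-likelihood test after TMM normalisation and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Positive log2 values mean higher in p(A)/p(A) cells. Before the data were examined, 17 gene lists, the design of each test, a set of other settings and the rule for naming genes were fixed. The lists were T-lineage factors, the T-cell receptor programme, natural killer and innate lymphoid genes, gamma-delta T cell genes, progenitor genes, Notch targets, IL-7 and survival genes, myeloid and mast cell markers, B-lineage markers, erythroid markers, stromal markers, cohesin and CTCF, cell cycle genes, T-cell leukaemia genes, neighbours of Bcl11b, immediate-early genes and sex-linked genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it, and adjusted over the lists. The rule named Bcl11b first, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, then up to 4 changed members of each list by p, or up to 2 by expression where none changed. List members named beyond that rule were chosen after their values were seen, and the text says so. Some genes that the rule named are not reported here.

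Replicates are separate samples by their labels, and nothing in the labels says that they came from separate animals or cultures. The p-values therefore measure the spread between these samples. By Xist and Y-linked reads each genotype of the RNA-seq held a female library and male ones, so its libraries were not all from the same animal. Whether those of the same sex came from separate animals is not known, and the spread between them may be technical. A chi-square statistic per gene between libraries of a group was at least 4.55, so no library was counted as a copy of another. That lowest value was of p(A)/p(A) 1 with p(A)/p(A) 2, which were far closer than the other pairs (23.1 to 66.7).

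Regions were compared with bedtools 2.31.1, counting an overlap of at least 1 bp as shared, after merging the lists compared where presence was counted per library. The lists give presence or absence alone, and with 2 libraries per genotype no exact test of a single region can pass the threshold, so regions found in both libraries of one genotype and neither of the other were counted and set beside the other 2 splits of the same 4 libraries. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only. The region around Bcl11b was fixed from the literature as 108 to 110 Mb of chromosome 12 in mm9. Regions in it were counted per 1 Mb bin and ranked among all such bins, and percentiles are given for some of the counts. Region lists are ordered by strength as far as checked, since regions at the top of a list recurred more often in its partner than regions at its end in each of 12 pairs examined.

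Hi-C values were compared as differences between matrices for bin pairs at least 2 bins apart, and as percentiles among pairs at the same distance and among equal blocks along the diagonal. A first principal component of the row correlation matrix was computed as well, oriented to be positive where H3K4me3 regions are frequent. That component was not part of the fixed design and was chosen after the values were seen. Bins at 0 for more than 0.5 of their partners were left out of it.

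Each step was tested on simulated data. In the comparison of p(A)/p(A) with wild type, on 12568 genes, the RNA-seq step recovered 21.5% of 65 genes changed by 0.5 in log2. It recovered 76.6% of 64 changed by 1 and 91.3% of 69 changed by 2, and 9 of its 135 calls were false. Far fewer genes were changed there than the 35.2% called in the data, so these rates cannot be carried over to the data. The region step recovered 100% of regions planted without noise, which checks the counting of overlaps only. The Hi-C step recovered a planted block of lower contacts with a median difference of -0.52. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and, as an alternative test, DESeq2 1.42.0 were used. The alternatives tried were other normalisations, tests and filters, a replicate block, leaving out each library, a stricter overlap, equal numbers of regions per list, and centring or averaging of Hi-C values.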

Results

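The series asked how transcription of the noncoding RNA gene ThymoD bears on Bcl11b, the zinc-finger factor that fixes the T-cell fate of early thymocytes, and on the folding of the chromosome around it. RNA-seq covered 3 wild-type and 3 p(A)/p(A) DN2 libraries, with between 24533937 and 28991159 reads in genes. ATAC-seq and SMC3 ChIP-seq covered 2 libraries of each of the 3 genotypes. CTCF was mapped in 1 wild-type, 2 heterozygous and 1 p(A)/p(A) library, and H3K4me1, H3K4me3 and H3.3 in 1 library per genotype. The lists held 95407 to 111456 ATAC regions, 21673 to 30657 SMC3 regions, 32074 to 37985 CTCF regions, 33587 to 48671 H3K4me1 regions, 12914 to 17693 H3K4me3 regions and 3476 to 9303 H3.3 regions. Hi-C covered 1 wild-type and 1 p(A)/p(A) library. Wild-type cells treated with actinomycin D, an inhibitor of transcription, were profiled for SMC3 and RNA polymerase II with 1 control and 2 treated libraries per time, and 3 tumours of p(A)/p(A) genotype for SMC3 and ATAC.

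Bcl11b RNA fell by 3.90 on the log2 scale in p(A)/p(A) DN2 cells (SE 0.20, adjusted p = 2.22e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 446 ± 112 to 29.8 ± 3.18 CPM (SD, n = 3 each). The 3 wild-type libraries held 559, 334 and 446 CPM and the 3 p(A)/p(A) libraries 29.6, 33.1 and 26.8 CPM. Bcl11b lies on chromosome 12 between 107910403 and 108004145 in GRCm38. ThymoD itself has no entry of that name in the count table.

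The largest rises in p(A)/p(A) cells were of genes with scarce RNA in wild-type cells. Art5, an ADP-ribosyltransferase, rose by 6.73 (SE 0.69), the chloride channel Ano1 by 6.11 and Arhgap20 by 5.97. Dlk1, a membrane protein related to Notch ligands, rose by 5.06 (SE 0.18), from 4.58 ± 1.14 to 152 ± 14.4 CPM, the highest level among the 12 genes. Among the others were the nicotinic receptor subunit Chrna10 (5.64, SE 0.85), which neighbours Art5 on chromosome 7, Slc6a7 (5.51), Cgnl1 (5.50), the pseudogene Olfr1372-ps1 (5.50), Gas7 (5.30), the slow-muscle troponin Tnni1 (5.19) and Trpm1 (5.04). Wild-type counts were 10, 2 and 1 for Art5 and 6, 1 and 0 for Chrna10, and leaving out 1 library gave 6.25 to 8.23 and 5.11 to 7.67, so the size of these rises is uncertain. The largest fall was of Cd6, a co-receptor of the T-cell surface (-5.82, SE 0.28), from 7.73 ± 1.48 to 0.132 ± 0.0195 CPM. Behind it came Ttll9 (-5.01), the kinase Pak6 (-4.84), Bpifb4 (-4.73), the lipopolysaccharide-binding protein Lbp (-4.11), the ectonucleotidase Entpd1 (-4.08), the lysozyme Lyz2 of myeloid cells (-4.06), the ephrin receptor Epha2 (-4.00), Acvrl1 (-3.98), Mpzl2 (-3.92), Bcl11b and Drc1 (-3.90). Ttll9, Bpifb4, Lbp, Lyz2, Acvrl1, Mpzl2 and Drc1 were highest in wild type 2, which also had the highest mean of stromal markers.

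Of 12700 RNA-seq genes tested, 4467 (35.2%) differed between the genotypes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2130 higher and 2337 lower in p(A)/p(A) cells. Among these, 736 were higher and 919 lower by more than 1 on the log2 scale. The libraries of the groups did not overlap for 51.5% of tested genes, where chance gives 10%, and the first principal component, which separated the genotypes, held 74.5% of the variance. The count of RNA-seq genes changed in p(A)/p(A) DN2 cells dropped to 2737 without p(A)/p(A) 1 and to 2966 without p(A)/p(A) 2. By Xist and the Y-linked genes, wild type 2 and p(A)/p(A) 3 came from female mice (46635 and 85887 Xist reads) and the other libraries from males (at most 707). With sex as a covariate 5498 genes differed, and without those female libraries 3988.

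**Figure D1:**
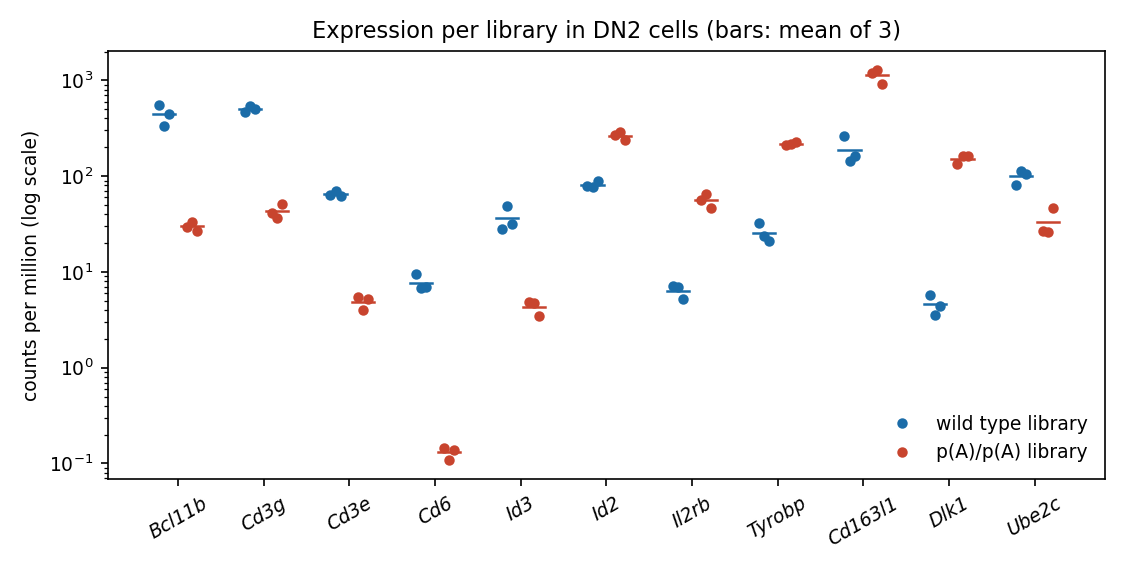
Expression of 11 genes in each DN2 library, in CPM on a log axis. Points are libraries and bars are means of 3, in blue for wild type and red for p(A)/p(A). Bcl11b stood at 446 CPM in wild type and 29.8 in p(A)/p(A) cells, and Dlk1 at 4.58 and 152.

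Genes of natural killer and innate lymphoid cells rose as a group. Of 24 tested, 21 were higher in p(A)/p(A) cells, 2 lower and 1 not past the threshold, and 23 differed when adjusted over the list alone. Il2rb, the shared receptor chain for IL-2 and IL-15, rose by 3.14, the signalling adaptors Tyrobp and Fcer1g by 3.09 and 2.14, and Id2, an inhibitor of E proteins needed by innate lymphocytes, by 1.72. Id2 reached 265.5 ± 25.5 CPM from 80.8 ± 6.38 in wild type. Among members picked after their values were seen, the factors Zbtb16 and Eomes rose by 3.22 and 4.30 and the natural killer receptor Ncr1 by 4.01. Members against the trend were Ifng (-2.16) and Nkg7 (-1.16), genes of effector lymphocytes, again picked after their values were seen. The list's median was 2.06 (camera, adjusted p = 6.33e-09), and adjusted p = 0.296 with an estimated correlation.

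The T-cell receptor programme fell. Of 23 genes, 16 were lower in p(A)/p(A) cells, 1 higher and 6 not past the threshold, with 18 different when adjusted over the list alone. The invariant receptor chains Cd3e (-3.73), Cd3g (-3.55) and Cd3d (-3.07) fell, Cd3g from 505 ± 39.5 to 43.1 ± 7.33 CPM. Cd5, a brake on receptor signalling, fell by 2.91, and the recombination genes Rag2 (-0.92) and Dntt (-1.28) fell as well, all 3 picked after their values were seen. Themis, which acts in thymocyte selection, was the member that rose (0.98), and Rag1 (-0.20), Ptcra (1.07), Cd2 (1.08), Cd28 (-0.38) and Cd27 did not pass the test, all of them picked after their values were seen. The list's median was -0.47 (camera, adjusted p = 1.24e-05), and adjusted p = 0.872 with an estimated correlation.

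Most cell cycle genes fell. Of 22, 21 were lower and 0 higher in p(A)/p(A) cells, and the helicase gene Mcm3 (-0.74), picked after its value was seen, was the exception, although all 22 differed when adjusted over the list alone. The ubiquitin-conjugating enzyme Ube2c of mitosis fell by 1.60, and the kinase Plk1 (-1.52), the spindle gene Tpx2 (-1.45) and Birc5 (-1.44), a regulator of chromosome segregation, fell as well. The list's median was -1.29 (camera, adjusted p = 1.55e-07), and adjusted p = 0.872 with an estimated correlation. With fry the list did not pass (adjusted p = 0.0650). The list's mean log2 CPM was 6.92, 7.65 and 7.42 in wild type and 5.86, 5.85 and 6.54 in p(A)/p(A) libraries, and it was highest in the female library of each genotype. Of 9 stromal markers tested, 4 were lower (Acta2 -1.38, Col1a2 -1.79, Col1a1 -1.87 and Fn1 -1.83), 0 higher and 5 not past the threshold. When adjusted over the list alone, 5 differed. Each of the 4 lost its call in some other setting. As a list, stromal markers did not pass (median -1.38, camera, adjusted p = 0.0925, and 0.872 with an estimated correlation). Their mean log2 CPM was 4.13, 4.98 and 4.50 in wild type and 2.70, 4.14 and 2.77 in p(A)/p(A) libraries.

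T-lineage factors went both ways, since of 16 genes 4 were higher, 4 lower and 8 not past the threshold, with 8 different when adjusted over the list alone. Besides Bcl11b, Id3, an inhibitor of E proteins (-3.06), and the repressor Gfi1 (-0.90) fell, while Gata3, a master factor of T cells, rose by 0.69. The Notch-driven factor Tcf7 (0.20), picked after its value was seen, did not pass the test. The list's median was 0.04, its mean -0.33 and its camera direction up (adjusted p = 0.955). Of 6 gamma-delta T cell genes, 4 were higher, 1 lower and 1 not past the threshold, with 5 different when adjusted over the list alone (camera, adjusted p = 0.283). The scavenger receptor Cd163l1 rose by 2.57 to 1129 ± 184 CPM, and the factor Maf by 2.13, while Sox13, an early gamma-delta factor, fell by 1.92. Of 17 progenitor genes, 4 rose, 6 fell and 7 did not pass, with 12 different when adjusted over the list alone (camera, adjusted p = 0.851): the stem cell factor receptor Kit rose by 1.13, Bcl11a by 0.87 and Tal1 by 0.81, and Nfe2 fell by 1.19.

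Of 10 Notch receptors and targets, 2 rose, 2 fell and 6 did not pass, with 6 different when adjusted over the list alone (camera, adjusted p = 0.698). The receptor Notch3 (-1.25) and Myc (-0.43) fell, and the IL-2 receptor chain Il2ra and Igf1r rose by 0.58 and 0.57. Of 12 IL-7 and survival genes, 1 rose, 2 fell and 9 did not pass, with 6 different when adjusted over the list alone (camera, adjusted p = 0.364). The IL-7 receptor Il7r rose by 0.99, while Cish, a target of STAT5 (-2.92), and Stat5b (-0.21) fell. Of 10 myeloid and mast cell markers, 3 rose, 2 fell and 5 did not pass, with 5 different when adjusted over the list alone (median 0.19, mean -0.13, camera direction up, adjusted p = 0.723). The Fc receptor Fcgr3 rose by 3.50 and the mast cell protease Cpa3 by 0.92, and Lyz2 (-4.06) and Cd33 (-1.38) fell. Of 8 B-lineage markers 1 fell, Cd79b of the B-cell receptor (-1.28), and 7 did not pass, with 1 different when adjusted over the list alone (median -1.20, camera, adjusted p = 0.317).

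Of 11 cohesin and CTCF genes, 1 rose, 3 fell and 7 did not pass, with 4 different when adjusted over the list alone (camera, adjusted p = 0.283). Cdca5, which stabilises cohesin in dividing cells (-1.07), the subunit Smc1a (-0.48) and Ctcf (-0.21) fell, while the loader subunit Mau2 rose by 0.28. Of 10 T-cell leukaemia genes, 2 rose, 3 fell and 5 did not pass, with 5 different when adjusted over the list alone (camera, adjusted p = 0.782), with Lmo1 lower (-1.92) and Fbxw7 higher by 0.31. Of 14 tested genes flanking Bcl11b, itself included, 2 rose, 2 fell and 10 did not pass, with 4 different when adjusted over the list alone (camera, adjusted p = 0.698). Ccdc85c rose by 1.59 and Evl, a regulator of actin, by 0.49, and the cyclin Ccnk fell by 0.29. With fry this list passed (adjusted p = 0.00714), as did the T-cell receptor programme (0.00125) and the natural killer and innate lymphoid genes (6.09e-04). The flanking list holds Bcl11b itself, so its result with fry cannot be read as a change of the other genes in it. Of 11 immediate-early genes 1 fell, Atf3 (-1.44), and 10 did not pass, with 0 different when adjusted over the list alone (camera, adjusted p = 0.364). The 5 sex-linked genes did not pass (median 0.20, mean 0.35, camera direction down, adjusted p = 0.955, with 0 different when adjusted over the list alone), with Xist at 0.87 and Ddx3y at 0.20. Of the erythroid markers Klf1 alone was tested (-0.24), and it did not pass.

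**Figure D2:**
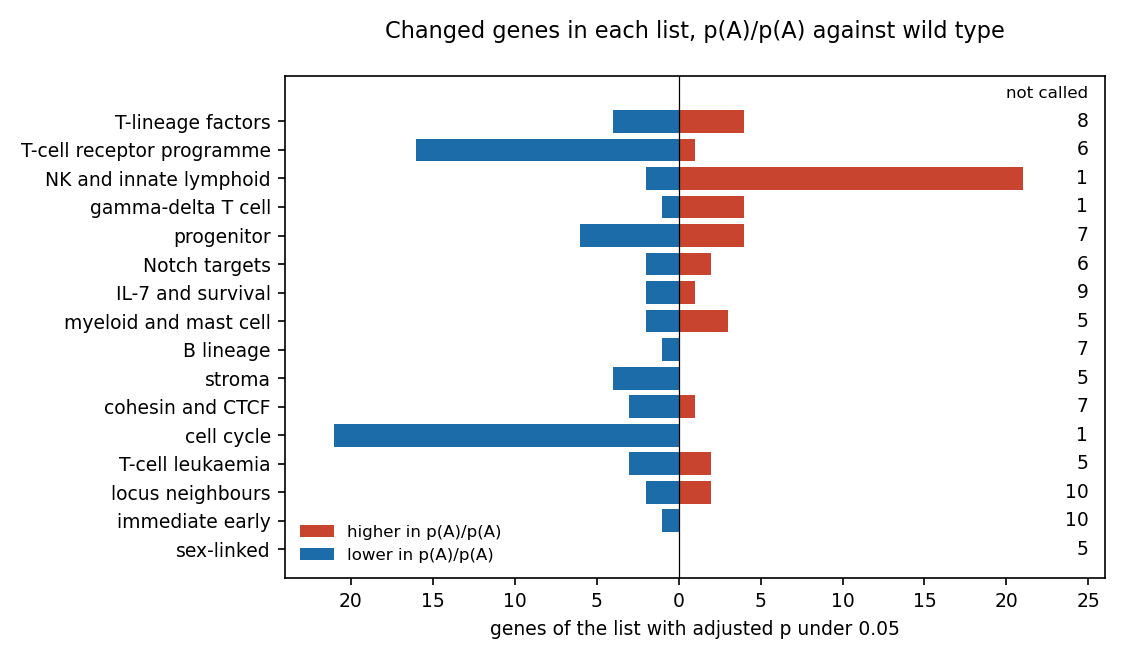
Number of genes in each of 16 lists that were higher (red, to the right) or lower (blue, to the left) in p(A)/p(A) than in wild-type DN2 cells, with the number not past the threshold at the right edge. Of the natural killer and innate lymphoid genes 21 were higher, and of the cell cycle genes 21 were lower.

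The megabase from 108 to 109 Mb of chromosome 12 (mm9), part of the stretch fixed for Bcl11b and its distal enhancer, lost its H3K4me1 regions in p(A)/p(A) cells. H3K4me1, a mark of enhancers, had 49 regions there in wild type (percentile 91.5 of 2644 bins), 36 in heterozygous and 0 in p(A)/p(A) cells, and 48 merged regions were in wild type and not in p(A)/p(A) cells. H3K4me3, a mark of promoters, had 5, 1 and 0 regions there, and H3.3, a histone variant of active chromatin, had 2, 0 and 0. In the next megabase, H3K4me1 had 47, 63 and 30 regions in the same order. In p(A)/p(A) cells each 40 kb bin from 109 to 109.4 Mb held 0 as well (5, 5 and 0 at 109160001 to 109200000). The absence thus ran past 109 Mb. Genome-wide, 38.5% of wild-type H3K4me1 regions (95% interval 38.0 to 38.9), 72.7% of H3K4me3 regions (72.0 to 73.4) and 3.64% of H3.3 regions (3.17 to 4.17) were found again in p(A)/p(A) cells. In heterozygous cells the shares were 60.1%, 62.0% and 12.8%, so wild-type H3K4me3 regions recurred less often there than in p(A)/p(A) cells. The heterozygous H3K4me3 list was also shorter (12914 regions against 14999), which can lower its share. For H3K4me1 and H3.3 the heterozygous lists were longer (48671 regions against 33587, and 9303 against 3476), which can raise their shares. These marks had 1 library per genotype, so the differences have no replicate check, and with a reciprocal overlap of at least 50% the H3K4me1 share was 16.3%.

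CTCF and SMC3, a subunit of cohesin, had fewer regions in the same megabase of p(A)/p(A) cells. SMC3 had 4 and 8 regions there in wild type, 4 and 5 in heterozygous and 1 and 3 in p(A)/p(A) libraries. An SMC3 region at 108356614 to 108356941 was present in both wild-type and both heterozygous libraries and in neither p(A)/p(A) library, and a CTCF region at 108356533 to 108356970 was in the wild-type and 1 of 2 heterozygous libraries and not in the p(A)/p(A) library. A second SMC3 region at 108945562 to 108945915 was found in both wild-type libraries only. CTCF had 4 regions there in wild type, 3 and 2 in heterozygous and 1 in p(A)/p(A) cells, and the regions at 108324383 to 108324832 (both heterozygous libraries) and 108387164 to 108387436 (neither) were also absent from the p(A)/p(A) library. Wild type and p(A)/p(A) had 1 CTCF library each, so these absences have no replicate check. Between 109 and 110 Mb, SMC3 regions at 109576832 to 109577147, 109726008 to 109726383 and 109767360 to 109767797 were gained in both p(A)/p(A) libraries. The SMC3 region at 109660891 to 109661234 was lost. Of 42 merged CTCF regions there, 7 were in the wild-type and not the p(A)/p(A) library and 1 was the reverse, again without a replicate check.

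Genome-wide, CTCF and SMC3 regions differed little beyond the spread between libraries. Of 37985 wild-type CTCF regions, 86.0% (85.7 to 86.4) were found again in p(A)/p(A) cells, and 91.7% of the p(A)/p(A) regions in wild type, against 86.0% and 83.96% between the heterozygous libraries. For SMC3, 2800 merged regions were in both libraries of one homozygous genotype and neither of the other, while the other splits of these 4 libraries gave 2869 and 2181. Wild type against heterozygous gave 2320 (other splits up to 2677) and heterozygous against p(A)/p(A) 2551 (up to 2888). In each comparison a split that mixed the genotypes gave the higher count.

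ATAC regions, which mark open chromatin, separated the labelled genotypes, but their labels are in doubt. The libraries labelled wild type and p(A)/p(A) differed at 10316 merged regions (other splits 7893 and 6300), those labelled wild type and heterozygous at 16557 (up to 6369), and those labelled heterozygous and p(A)/p(A) at 17851 (up to 7597). Between 108 and 109 Mb the libraries labelled wild type had 27 and 24 regions, those labelled heterozygous 16 and 13, and those labelled p(A)/p(A) 34 and 27. ATAC regions at 108384915 to 108385113, 108385381 to 108385529 and 108386097 to 108386247 were in both libraries labelled wild type, in 2, 1 and 2 of those labelled heterozygous and in neither labelled p(A)/p(A), and those at 108255127 to 108255246 and 108714625 to 108714766 were the reverse. The names given to the deposited lists state another genotype than the labels for each of the 6 libraries: heterozygous for those labelled wild type, knockout for those labelled heterozygous and wild type for those labelled p(A)/p(A), so the direction of these differences is open. The lists labelled wild type held 17 and 2 regions on Y and the other 4 between 65 and 87, and the sex of the donors of these libraries is not given in the sources used here.

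Hi-C contacts within the Bcl11b stretch were fewer in p(A)/p(A) cells. Of 1176 pairs of 40 kb bins between 108 and 110 Mb, 934 (79.4%, 95% interval 77.0 to 81.7) had a lower log2 ratio of observed over expected contacts in p(A)/p(A) than in wild-type cells, with a median difference of -0.57 (SD 0.99 across pairs). That median lay at percentile 0.0733 among 2727 equal blocks of chromosome 12. Contacts between the first and second megabase were lower in 87.3% of pairs (median -0.94), those within the first in 78.6% (-0.49) and those within the second in 62.3% (-0.15). Bin pairs share bins and reads, so the intervals are too narrow, and there was 1 library per genotype.

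The component that sorts chromosome 12 into active and inactive compartments changed along the same stretch. Over 2808 bins the components of the genotypes had a correlation across bins of 0.972, and 97 bins (3.45%) changed sign. The longest run that changed, 28 bins from 108240001 to 109360000, went from positive, the side rich in H3K4me3, in wild type (mean 0.31) to negative in p(A)/p(A) cells (mean -1.22), and the next longest runs were of 4 bins. One of these, from 107080001 to 107240000, also went from positive to negative (0.30 to -0.39), and the bins from 107000001 to 108240000 were all lower in p(A)/p(A) cells, so the change reached beyond the stretch. The 20 bins with the largest falls of the chromosome all lay between 108 and 110 Mb. At 1 Mb resolution, the contact profile of the bin at 108 Mb with the rest of chromosome 12 had a correlation of -0.63 between genotypes, where the median of 115 bins was 0.915, and its profile with other chromosomes one of -0.22, where the median was 0.367. Both were the lowest of the chromosome. The bin at 109 Mb had 0.438 with the rest of chromosome 12, also among the lowest (percentile 1.74), and 0.488 with other chromosomes (percentile 73.9).

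**Figure D3:**
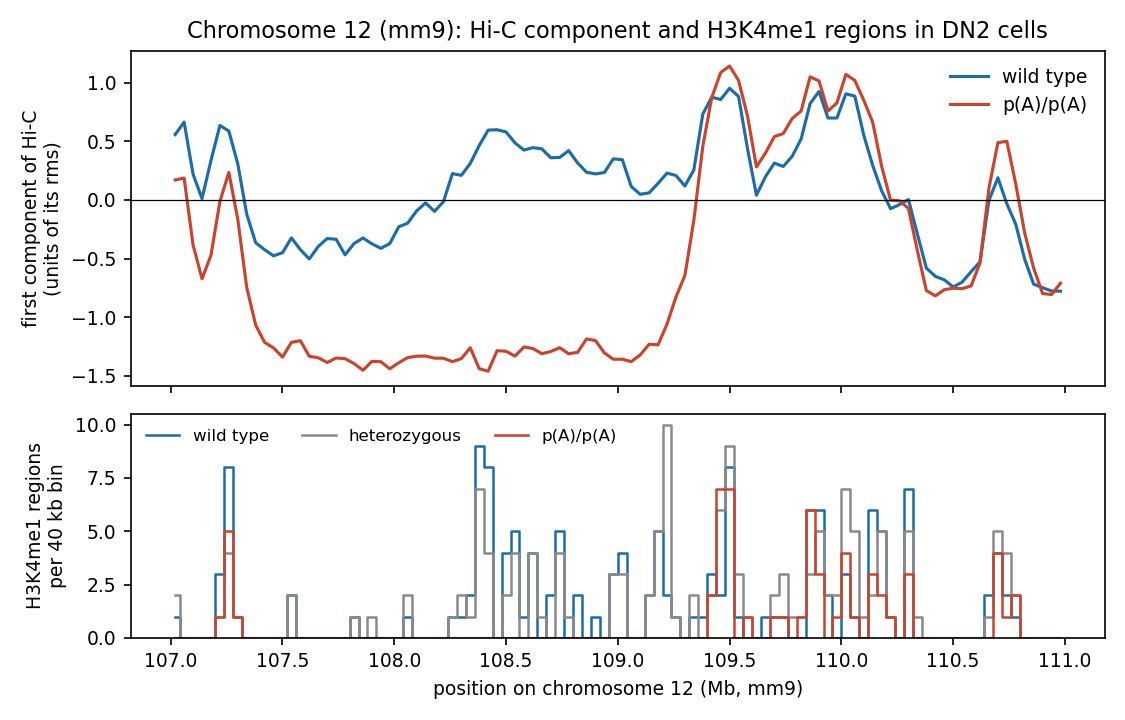
First component of the Hi-C correlation matrix (upper axes, in units of its root mean square) and H3K4me1 regions per 40 kb bin (lower axes) along chromosome 12 from 107 to 111 Mb in mm9. Lines are wild type in blue, heterozygous in grey and p(A)/p(A) in red. From 108240001 to 109360000 the component averaged 0.31 in wild type and -1.22 in p(A)/p(A) cells.

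Compared with the matrices of B-lineage cells, that of wild-type DN2 cells had more contacts across the Bcl11b stretch as a whole, though fewer within its second megabase. The B-lineage matrices come from another series and no cell type had a replicate matrix. A difference of cell type therefore cannot be told apart from one between studies. Bin pairs share bins and reads, so the intervals are again too narrow. Of 741 pairs of 50 kb bins, 60.1% had a higher log2 ratio in DN2 than in pre-pro-B cells (95% interval 56.4 to 63.6, median difference 0.22) and 59.6% than in pro-B cells (56.0 to 63.2, median 0.31), at percentiles 95.01 and 93.6 of equal blocks between 100 and 120 Mb. Contacts between the first and second megabase were higher in DN2 cells for 74.4% of pairs against pre-pro-B (0.50) and 66.9% against pro-B cells (0.59). Within the first megabase the shares were 64.9% and 80.7%, and within the second, 21.6% against each, with medians of -0.43 and -0.42. In a component computed from 100 to 120 Mb alone, which differs from that of the whole chromosome, 25 of 40 bins in the stretch were on the positive side of the component in DN2, 12 in pre-pro-B and 2 in pro-B cells.

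After actinomycin D at 10 µg/ml, most SMC3 regions of the control were found again at 15 and 30 min and a minority at 60 min. Of the control's SMC3 regions, the treated libraries held 85.8% and 68.6% at 15 min, 83.7% and 88.7% at 30 min, and 40.4% and 16.5% at 60 min, where the treated lists had 7894 and 3024 regions against 16649. Between untreated cells, the 30 min control held 82.6% of the 15 min control regions, the 15 min control 93.3% of the 30 min ones, and these controls 92.8% and 89.9% of the 60 min ones. RNA polymerase II regions were found again at 89.7% and 61.1% at 15 min and 87.8% and 89.5% at 30 min, against 76.9% and 87.1% in the untreated control of the other time. The 60 min SMC3 libraries were made with another antibody lot, and the untreated 60 min control held 54.5% and 59.7% of the regions of the 15 and 30 min controls. With equal numbers of regions taken from the top of each list, a setting chosen after seeing the data, the mean share at 60 min was 51.7% against 28.5%. The short treated lists cap the share at 60 min, and 85.2% and 90.9% of their regions were in the control. A loss of regions was therefore not set apart from fewer regions called.

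SMC3 regions without CTCF were found again less often than those with CTCF. At 60 min, SMC3 regions with CTCF were kept at 42.8% and 17.6%, and regions with polymerase II but no CTCF at 13.4% (9.14 to 18.6) and 2.30% (0.752 to 5.29) of 217. Regions with neither were kept at 8.78% and 2.04% of 979. In the other untreated controls the shares at the same 60 min control regions were 96.0% and 93.5% with CTCF, 52.1% and 43.3% with polymerase II and no CTCF, and 50.7% and 44.1% with neither. At 15 min, regions with polymerase II and no CTCF were kept at 68.1% and 31.3% of 595, and at 30 min at 60.8% and 67.0% of 339, against 89.2% and 74.0%, and 86.8% and 91.3%, with CTCF. In the other early untreated control the shares were 41.8% against 87.3% with CTCF for the 15 min regions and 70.8% against 95.5% for the 30 min ones. The classes at 60 min rest on the polymerase II regions of the 30 min control.

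**Figure D4:**
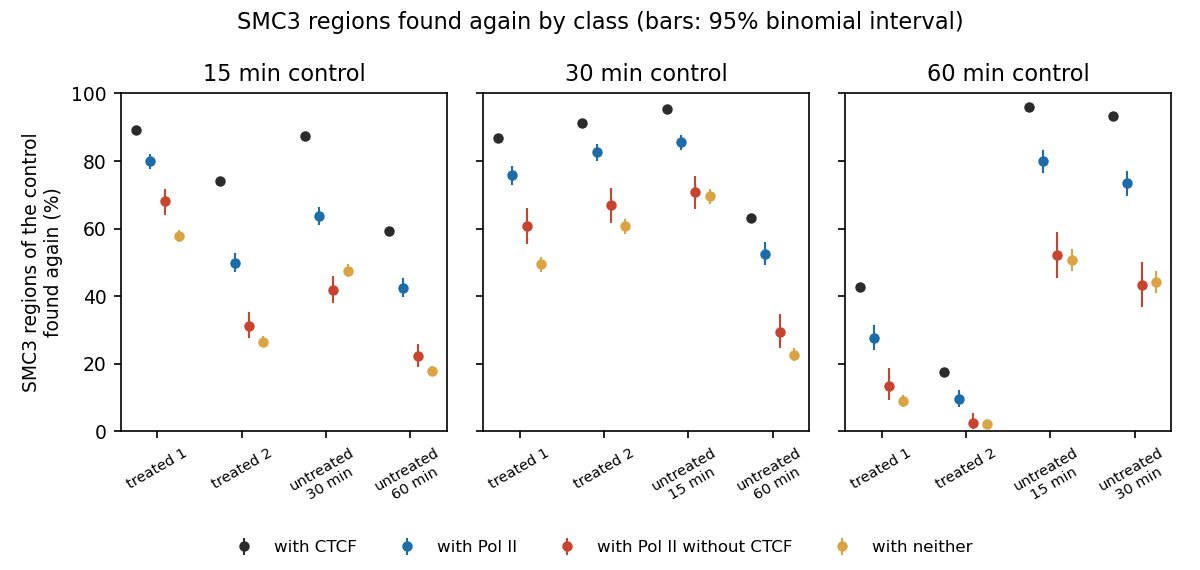
Share of the SMC3 regions of each control found again in 2 treated libraries and in the untreated controls of other times, by class, in percent. Points are libraries and bars are 95% Clopper-Pearson intervals. At 60 min the share with polymerase II and no CTCF was 13.4% and 2.30%, against 42.8% and 17.6% with CTCF.

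Tumours of p(A)/p(A) genotype had 11315 SMC3 regions and 24316 ATAC regions in common to all 3, from lists of different length and region width. The mean share of regions found in another tumour was 67.0% ± 11.9 (SD over pairs) for SMC3 and 50.0% ± 13.7 for ATAC, where DN2 libraries shared 58.5% to 84.4% and 65.1% to 81.9% with one another. Of merged regions, 33.4% for SMC3 and 18.6% for ATAC were in all 3 tumours. Tumour SMC3 regions were found in DN2 libraries at means of 73.6%, 74.4% and 63.2% for tumours 3, 5 and 6, and tumour ATAC regions at 49.8%, 60.5% and 66.2%. Per the labels the tumour cells were cultured in different ways or taken fresh, so tumours were not treated as replicates. With a reciprocal overlap of at least 50% the ATAC mean was 29.1%.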

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

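The tests given here were all chosen after the DN3 matrix was seen. The Hi-C matrix of DN3 cells from RAG-deficient mice was not part of any comparison. It was read for the 3 bins holding Bcl11b and for 29 other columns spaced along the chromosome. Of these 3, the bins starting at 107900001 and 107950001 of chromosome 12 in mm10 had contacts above those of all 29 columns. That held at each distance given, on the side of lower coordinates. The balanced contacts of the bins starting at 107900001 and 107950001 were 260 and 235 at 0.2 to 0.5 Mb, where the highest of the other columns had 150, and 222 and 203 at 0.5 to 0.8 Mb, where it had 124. The bin starting at 108000001 had 110.4 and 111.9 at these distances, under the highest of the other columns. At 0.8 to 1.2 Mb the bins starting at 107900001, 107950001 and 108000001 had 265, 290.1 and 222, against a highest of 171 and a median of 33.7. At 1.2 to 2 Mb they had 161, 205 and 389, against a highest of 137. On the side of higher coordinates the same bins had 14.3, 14.0 and 18.8 at 0.8 to 1.2 Mb, under the median of 41.3. No control genotype was measured in DN3 cells, and no explanation was tested.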

How the results depend on the processing

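Alternatives with sex as a covariate, without the female libraries, without the library with most stromal RNA in each group, and with equal numbers of regions from the top of each list were chosen after seeing the data. Planned lists of best-scored regions were not run, since the lists carry no score. Over 145 results and 1440 alternative values, 1299 were kept and 22 reversed. None of the reversed values was of a named gene or list that differed between genotypes. Kept values had the same direction and side of the threshold, stayed within a spread or interval, or, for counts, stayed within a fixed fold. Actinomycin D shares with a treated library left out could not leave their spread, since it came from those same libraries. Of all 4467 genes, 1 had the opposite sign without the female libraries and 1 without the most stromal libraries. Of 74 named genes, 13 lost their call in some setting (among them Il7r, Stat5b, Acta2, Col1a2, Col1a1, Fn1, Smc1a, Mau2, Ctcf, Fbxw7, Ccnk and Atf3) and 0 gained one.

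The count of RNA-seq genes changed in p(A)/p(A) DN2 cells, 4467, was 4745 with DESeq2, 4537 with limma-voom and between 2737 and 5402 when 1 library was left out, lowest without p(A)/p(A) 1 (2737) and p(A)/p(A) 2 (2966). It was 3003 without the library with most stromal RNA in each group. Fewer libraries were tested in these settings, yet leaving out 1 library also gave as many as 5402. The libraries p(A)/p(A) 1 and p(A)/p(A) 2 were the closest pair (chi-square 4.55 per gene). Whether their small spread raised the count of 4467 was not tested, nor was any other cause. With the replicate block 3973 genes differed, of which 3831 were among the 4467. The numbers do not pair the libraries: the correlations of same-numbered libraries' deviations were 0.24, -0.23 and -0.13, and not every library went best with its own number. The count of 3 lists fell to 0 with an estimated correlation. As a list, stromal markers passed the threshold with the replicate block (adjusted p = 0.00226), without p(A)/p(A) 2 (9.97e-04) and without the library with most stromal RNA in each group (5.30e-04), and immediate-early genes without the female libraries (0.00186).

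Reversed values were all of results that did not pass the test. When 1 library was left out, the log2 fold change of Klf1 ran from -0.442 to 0.0395 (without wild type 1), the log2 fold change of Xist from -6.92 to 5.74 and the log2 fold change of Ddx3y from -0.39 to 0.79. Xist also reversed to -1.10 with limma-voom, -3.36 with the replicate block, -6.92 without p(A)/p(A) 3, -0.79 with sex as a covariate and -2.06 without the female libraries. Ddx3y was -0.39, -0.31 and -0.12 without wild type 2, p(A)/p(A) 1 and p(A)/p(A) 2, and -0.71 without the library with most stromal RNA in each group. Lists reversed their direction at adjusted p, for T-lineage factors, of 0.995 with the replicate block, 0.628, 0.993 and 0.915 without wild type 2, p(A)/p(A) 1 and p(A)/p(A) 2, 0.694 without the female libraries and 0.548 without the most stromal libraries. For progenitor genes they were 0.733 without wild type 2 (0.632 to 0.915 when any 1 library was left out) and 0.591 without the most stromal libraries, and for sex-linked genes 0.899, 0.906 and 0.697 without wild type 1, wild type 3 and p(A)/p(A) 3 (0.628 to 0.906 when any 1 was left out) and 0.511 without the female libraries. The cause was not tested.

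With a reciprocal overlap of at least 50%, ATAC regions that differed between wild type and p(A)/p(A) as labelled were 15576, the shares of wild-type H3K4me1, H3K4me3 and H3.3 regions found in p(A)/p(A) cells 16.3%, 68.3% and 2.28%, the polymerase II share at 30 min 80.2% and the share between tumours' ATAC regions 29.1%. Equal numbers of regions gave 89.7% for CTCF, 47.1%, 84.6% and 5.21% for the 3 histone marks, 51.7% for SMC3 at 60 min and 72.2% for polymerase II at 30 min. Between 108 and 109 Mb they gave 21 H3K4me1 regions in heterozygous and 3 H3K4me3 regions in wild-type cells, and 5 and 1 SMC3 regions in wild type 2 and p(A)/p(A) 2. Leaving out replicate 1 or 2 raised the counts that differ to between 53676 and 55864, 60284 and 63130, and 55428 and 62172 for the ATAC comparisons and to between 14645 and 16774, 13904 and 14052, and 14883 and 16470 for SMC3, because a single library per genotype then decides presence. Means over 3 by 3 bins gave 83.3% of Hi-C pairs lower in p(A)/p(A) cells. Centring on pairs at the same distance gave 65.3% of pairs higher in DN2 than in pre-pro-B and 70.2% than in pro-B cells, and it moved nothing for p(A)/p(A) against wild type because the median difference was 0 at most distances. Regions at the end of a list recurred less often than those at its top, and an effect of depth was not tested.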

Other observations

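Of the tests reported here, those of library splits, stromal RNA at Dlk1, list length in the ATAC libraries, less reproducible calls of SMC3 regions at each time and the joint explanation of SMC3 regions at 60 min were chosen after the result was seen, and the others before. The tumours had SMC3 and ATAC regions around Bcl11b. Between 108 and 109 Mb of chromosome 12 (mm9) tumours 3, 5 and 6 had 9, 2 and 15 SMC3 regions (percentiles 68.5, 41.2 and 72.5 among 1 Mb bins), where p(A)/p(A) DN2 libraries had 1 and 3. They had 47, 26 and 34 ATAC regions there. After actinomycin D, SMC3 had 10 and 5 regions there at 15 min (control 7), 5 and 6 at 30 min (control 5) and 2 and 1 at 60 min (control 5). At 60 min the treated lists were short as a whole (7894 and 3024 regions against 16649). The bin stood at percentiles 52.1 and 61.7 in them against 53.9 in the control, so a loss particular to it was not shown.

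Meg3 and Rian, noncoding RNA genes imprinted with Dlk1 and picked after their values were seen, rose with it in p(A)/p(A) cells, by 4.83 (SE 0.52) and 4.93 (SE 0.62) on the log2 scale. RNA from stromal cells is argued against, since the stromal markers had a median of -1.38 and 0 of 9 rose. Nor did the 11 genes tested between Bcl11b and Dlk1 rise together (median -0.0895, with 2 higher and 2 lower), nor 14 imprinted genes elsewhere (median 0.13, with 2 higher). A change of the cluster with the genotype is a hypothesis that these values leave open. A strain variant carried along with the targeted allele was not tested and stays open as well.

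The ATAC libraries labelled heterozygous had the fewest regions between 108 and 109 Mb. List length is argued against, since with 95407 regions per list the libraries labelled heterozygous had at most 13 regions there and those labelled p(A)/p(A) 27. H3K4me1 regions lost in p(A)/p(A) cells were covered 1.52 and 1.54 times as often as gained ones by libraries labelled heterozygous. The ratios were 1.82 and 1.82 for those labelled wild type, and 1.86 and 1.89 for those labelled p(A)/p(A). That is the order that the names of the deposited lists would give. It came from gained regions, covered at 22.4% and 21.4% in libraries labelled heterozygous and 16.9% to 18.2% in the others. Lost regions were covered at 34.02% and 32.97% there, and at 31.9% to 33.9% in the others. By the names they would be covered less often there, which was not seen. Lists labelled heterozygous also covered the most sequence (11.8 and 11.3 Mb, the others at most 10.9), so the ratios cannot decide. The ATAC regions at 108384915 to 108385113, 108385381 to 108385529 and 108386097 to 108386247 were in neither library labelled p(A)/p(A). They were in 2, 1 and 2 of the libraries labelled heterozygous, an order that the labels would give. By the names they would be absent in wild type and present in the other genotypes, which is an order by genotype as well. These regions therefore cannot decide between labels and names. The labels may be interchanged, and an effect of the heterozygous genotype itself remains open as well.

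For SMC3 regions with polymerase II and without CTCF, kept less often than those with CTCF after actinomycin D, the ratio of the kept shares at 15 and 30 min lay below that of the other early untreated control in 3 of 4 treated libraries (0.423 against 0.479 at 15 min, 0.700 and 0.734 against 0.742 at 30 min, and 0.763 in the exception), and above those of the untreated 60 min control (0.378 and 0.468) in all 4. After matching on the place in the list, all 4 lay above the early untreated control (0.871 and 0.566 against 0.555, 0.796 and 0.801 against 0.780) and 3 of 4 above the 60 min one (0.641 and 0.682), so an effect of treatment was not set apart from less reproducible calls at these times. At 60 min the ratios were 0.312 and 0.131 against 0.542 and 0.463 in untreated cells. Those untreated lists held 28339 and 25094 regions and the treated ones 7894 and 3024. The gap can therefore come from list length, and less reproducible calls alone stay open. After matching on the place in the list the ratios were 0.506 and 0.321, which argues against weak regions alone. Weak regions and less reproducible calls together cannot be told apart from an effect of treatment, since the lowest matched ratio in untreated cells was 0.492. Loss of transcription may act on these regions, but the 60 min antibody lot and the short treated lists leave that untested.

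For the RNA-seq comparison, 6 libraries make 10 splits into 3 and 3, which never give a share under 0.1. The real split gave 4467 genes and the highest of the others 0, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For lists it gave 3 and the highest of the others 7, and 10 of the 10 splits gave at least 3. Every other split mixes the genotypes unevenly, so it keeps part of the genotype difference and adds the rest to the spread within groups. Which lists passed in those splits was not compared, so the count of lists cannot decide whether the list tests follow the genotype. For genes 1 of the 10 splits, the real one, reached 4467.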
